A study of Mus musculus with 12 samples.

How the data were processed

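The deposited file gives, per the submitters' processing notes, a methylation percent from 0 to 100 for each cytosine of 12 libraries, made by the authors with Trim Galore and Bismark 0.13.1 on mouse build mm9. It lists 8119606 positions and marks missing values with N. All coordinates are mm9.

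The file gives no sequence context, and it lists cytosines of CG and of GC. The context was found by matching exon sequences of the GENCODE M21 transcripts to the pattern of listed positions. Starting shifts of each chromosome came from a pattern search, and an exon was accepted only if its own pattern matched at least 8 listed positions exactly. This places sequence on mm9 by the listed positions alone, and no coordinate was converted between builds. It comes close to such a conversion and departs from the plan, which annotated genes only if an annotation of mm9 was given. Of 151231 exons 79090 were placed (52.3%), against 21 of 113158 at a false shift of 2017 bp (0.0186%). The context became known at 2255240 listed positions (27.8%), with 0 conflicts.

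Means and tiles used CpGs of placed exons, with both strands averaged, outside CCGG, the site of MspI. Means over CpGs that reached 20% used CpGs at 20% or more in at least 1 of the 10 libraries outside the pair. Tiles of 1 kb needed 3 CpGs measured in both libraries, and a difference of 25 points counted as higher or lower. Promoters and windows used cytosines that reached 20%, of which 98.7% were CpG among those of known context. For promoters the 20% had to be reached outside the pair. Windows used each library's own cytosines, at least 5, and CCGG sites remain in promoters and windows.

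Promoters ran from 1000 bp upstream to 500 bp downstream of the start of a placed first exon, with at least 6 cytosines, for 13326 genes, leaving out genes with provisional Gm numbers. The upstream part assumes that sequence next to the matched exon lies in the same order in mm9. The 27 imprinted windows and 6 gene lists (germline, pluripotency, fibroblast and feeder, trophoblast, neural and developmental genes) were fixed from general knowledge before the data were examined. A window was called imprinted if the WT embryo had 25 to 75% over at least 5 cytosines, which 23 were. Left out were Gpr1-Zdbf2 (94.1%), Ndn (17.9%) and the paternally methylated H19-Igf2 and Dlk1-Dio3 control regions, with 4 and 1 cytosines there. Only Rasgrf1 remained of the germline windows methylated on the paternal copy. The H19 promoter, Meg3 promoter, Nesp and Cdkn1c were classed as somatic windows. Named genes are listed genes that changed by at least 25 points and, among promoters with at least 10 cytosines, the 10 largest differences each way, of which the text gives the leading ones. A list of at least 3 measured genes was set beside 10000 random lists of similar level in the first library. Dense tiles have at least 20 CpGs.

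Outside the germline list, no listed gene passed 25 points in phESC passage, in early ahESCs against diploid cells, in any late comparison, or in any embryo or brain comparison. Aqp4 was lower in early phESCs than in diploid cells (81.1% and 48.3%) and than in ahESCs (73.8% and 48.3%), and Hoxc10 was lower in early phESCs than in ahESCs (56.9% and 25.4%).

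The test of passage over the 3 cell types was added after the results were seen.

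In a self-test, 100 tiles were raised and 100 lowered in a copy of the early diploid library at 20 simulated reads per CpG. Changes of 40 points were called in 99 and 98 tiles, with 4 false rises and 3 false falls in 24543 tiles. The software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.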

Results

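Cytosine methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads the CpG-rich fragments left by the enzyme MspI, in 12 mouse libraries. There is 1 library per group, so no value has a replicate error and the comparisons of single libraries were not tested. Androgenetic haploid embryonic stem cells (ahESCs, with a genome of paternal origin), parthenogenetic haploid embryonic stem cells (phESCs, with a genome of maternal origin) and diploid embryonic stem cells were each sampled at early and at late passage. Whole embryos at E15.5 (days of embryonic development) were wild type (WT), bimaternal (BM) or bipaternal (BP). The brain libraries were of BM at E19.5, BM adult and WT adult. The BM and BP samples carry deletions of differentially methylated regions per the labels, which do not say which regions. Windows inside a deleted region could not be marked, and a BM or BP value there would come from the remaining copy alone. The number of cytosines with a value ran from 3773871 in the BP embryo to 5903648 in the WT adult brain. The read depth behind each value is unknown, because the deposited values are percentages without coverage. The mean over exonic CpGs ran from 5.03% in late diploid cells to 18.2% in the BM E19.5 brain.

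The 12 libraries do not all cover the same sites, and this limits some comparisons. The late ahESC, late phESC, adult BM and adult WT libraries have values on the unplaced sequence of chromosome Y, at 4124, 2348, 2209 and 7697 positions, and are called the second library set. The other 8 libraries have none there and are called the first set. CCGG sites made up 2.39% of the exonic CpG cytosines with a value in the late phESC library, against 25.1% in the late ahESC library, 27.1% in the adult BM brain and 16.2% in the WT embryo. The late phESC library also stands apart in which positions have a value. Across positions, the correlation of presence was 0.0434, 0.0503 and 0.0121 with the other libraries of the second set, 0.193 to 0.333 with the first set, and 0.560 to 0.720 among those other 3. Comparisons of late haploid with early haploid or diploid cells, and of the adult with the E19.5 BM brain, cross the sets. For them no library set holds both groups, so the set and the group are not separated.

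In diploid embryonic stem cells, late passage went with a loss of methylation across the genome, with promoters of germline genes and nearly all maternally methylated imprinted regions among the sequences that lost it. Over all exonic CpGs outside CCGG sites the mean was 12.6% early and 4.85% late, a difference of -7.70 points. Among those that reached 20% in another library, it was 50.3% at early and 18.7% at late passage. Of 23797 tiles of 1 kb, 6904 fell by at least 25 points and 1 rose. Over all cytosines that reached 20% elsewhere, exonic or not, 36520 of 48630 tiles fell and 14 rose. Of the 12 measured germline genes that are silenced by promoter methylation in somatic cells, 8 fell, among them Tex101, which encodes a germ cell surface protein, from 81.1% to 36.3%, and Asz1, a gene of the piRNA pathway, from 61.3% to 18.3%. Of 18 maternally methylated germline windows 15 fell, for example Snrpn-Snurf from 54.3% to 1.42% and Kcnq1ot1, the control region of the Kcnq1 domain, from 50.6% to 1.11%.

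The other falls among listed germline genes were Slc25a31 from 47.2% to 12.3%, Fkbp6 from 45.1% to 11.1%, Dpep3 from 87.2% to 55.1%, Rpl10l from 33.1% to 2.49%, Sycp3 of the synaptonemal complex from 37.9% to 11.1% and Hormad1 from 37.5% to 11.5%. The median difference of the list was -28.7 points, at percentile 32.2 of random lists matched on early methylation, so the germline genes did not stand apart from other promoters of similar level. Of 5 measured neural genes, Aqp4, an astrocyte water channel, fell from 81.1% to 32.2% and Gfap, an astrocyte filament protein, from 64.5% to 20.6%. Among 6 measured developmental regulators Hoxc10 fell from 41.6% to 14.8%. None of the 3 measured trophoblast genes passed 25 points, and Hand1 stood at 19.7% and 6.21%. The 1 measured fibroblast gene, Twist2, stood at 30.1% and 6.16%. The 2 measured pluripotency genes were low at both passages, with Esrrb at 9.15% and 9.77% and Tbx3 at 5.02% and 4.47%.

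Over all measured promoters, listed genes included, 771 of 3929 fell and 3 rose. The largest falls outside the lists were at 4933431M02Rik (85.8% to 16.7%), Tpt1-ps3 (87.3% to 18.9%) and Ppp1r2-ps7 (85.4% to 17.3%), and Tenm2, a teneurin of neurons, fell from 75.04% to 7.91%. The 3 that rose were Fv1, a restriction gene against retroviruses, and Miip, which share a promoter on chromosome 4 (1.23% to 33.2%, mm9 position 147242088 to 147243588 for Fv1), and Abcc9 on chromosome 6 (7.49% to 32.9%). The exceptions among the maternal windows were already low at early passage, with Mcts2-H13 at 0.776%, Slc38a4 at 0.852% and Gnas-1A at 9.71%. Of 5 paternally methylated windows, of which only Rasgrf1 is a germline window, 3 fell. They were Rasgrf1 from 72.4% to 17.7%, the H19 promoter from 58.4% to 14.1% and the Meg3 promoter from 51.2% to 3.93%. The Rasgrf1 values rest on 11 and 5 cytosines. The H19-Igf2 and Dlk1-Dio3 control regions had too few cytosines in these libraries to count as measured. Nesp (3.26% and 1.69%) and Cdkn1c (5.18% and 1.83%) were low at both passages. Both diploid libraries are of the first set.

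In ahESCs, late passage also went with wide loss of methylation, some paternally methylated windows included, while the maternally methylated windows were already low at early passage. The mean over all exonic CpGs outside CCGG sites was 11.3% early and 5.95% late (-5.32 points). Among those that reached 20% in another library it was 48.8% early and 23.7% late. Of 21586 tiles, 4975 fell and 2 rose, and over all cytosines that reached 20% elsewhere 25146 of 39868 fell and 16 rose. Of 12 measured germline genes 4 fell, namely Tex101 (83.0% to 21.8%), Fkbp6 (58.0% to 11.4%), Asz1 (61.3% to 20.6%) and Slc25a31 (35.6% to 9.37%). None of the 17 maternal windows measured at both passages passed 25 points, with a mean difference of 2.34 points, and the late mean was 5.80% (SD 2.61). The highest of them at early passage, Mest, stood at 16.3%, so none could fall by 25 points.

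The median difference of the germline list was -20.6 points, at percentile 19.06 of matched random lists. Aqp4 fell from 74.1% to 19.2% and Hoxc10 from 56.9% to 26.2%, while Twist2 stood at 33.9% and 12.98%. Of 1896 promoters 539 fell and 1 rose. Rps19-ps5 fell from 80.9% to 9.56%, 4933431M02Rik from 81.9% to 10.8% and Tenm2 from 72.6% to 8.95%, and the potassium channel gene Kcnb2 fell from 82.1% to 20.9%. The paternally methylated Rasgrf1 window fell from 57.0% to 31.3%, and the Meg3 promoter from 44.1% to 9.77%. The H19 promoter stood at 35.1% and 16.4%, and Nesp and Cdkn1c were low at both passages. Cdh15 was the exception among the maternal windows at early passage, at 82.5%, and was not measured at late passage. This comparison crosses the library sets, and in the tiles that fell, by 39.2 points on average, the adult and E19.5 BM brains of the 2 sets differed by -3.27 points. CCGG sites, which remain in promoters and windows, stood 21.6 points below other CpGs of methylated tiles in the late library. This gap rests on 493 tiles, chosen as 60% or more at the other CpGs. The differences of Slc25a31 (-26.2) and Rasgrf1 (-25.8) lie close to the 25-point rule.

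**Figure D1:**
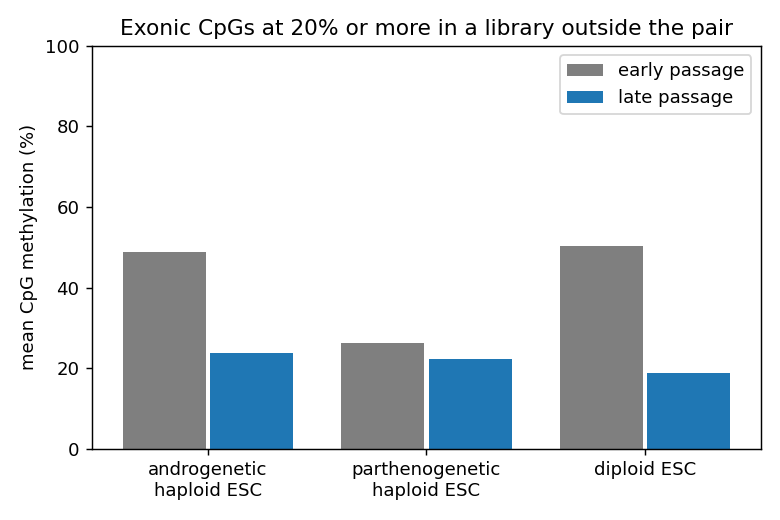
Mean CpG methylation in percent (vertical axis) at early and late passage in the 3 stem cell types, over exonic CpGs outside CCGG sites that reached 20% in a library outside the pair. Each bar is 1 library. The bars go from 48.8% to 23.7% in ahESCs, from 26.1% to 22.2% in phESCs and from 50.3% to 18.7% in diploid cells.

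In phESCs, methylation was already low at early passage, and few tiles changed by at least 25 points. The mean over all exonic CpGs outside CCGG sites was 5.98% early and 5.03% late (-0.953 points). Among those that reached 20% in another library it was 26.1% early and 22.2% late. Of 21252 tiles, 144 fell and 18 rose. None of the 12 measured germline genes passed 25 points, with a median difference of -6.01, and Tex101 stood at 42.1% and 32.1%. No maternal window of 18 passed 25 points, with means of 3.81% (SD 5.50) early and 4.83% (SD 3.75) late. The highest early window, Cdh15, stood at 24.9%, so none could fall by 25 points. Most of the germline genes also started under 25%, so the rule could not call a fall in them.

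Of 1184 promoters, 10 were lower and 2 higher by at least 25 points. Fv1 and Miip fell from 35.6% to 1.21% and 2810429I04Rik from 29.8% to 4.61%. Tmem267 and 3110070M22Rik, which share a promoter on chromosome 13, rose from 15.3% to 55.7%. The comparison crosses the library sets, and the late library holds few CCGG sites. Over the 3 cell types the late minus early differences over all exonic CpGs outside CCGG sites had a mean of -4.66 points (SD 3.42, n = 3 cell types), with p = 0.25 in a two-sided exact sign-flip permutation test, the smallest p that 3 pairs allow.

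**Figure D2:**
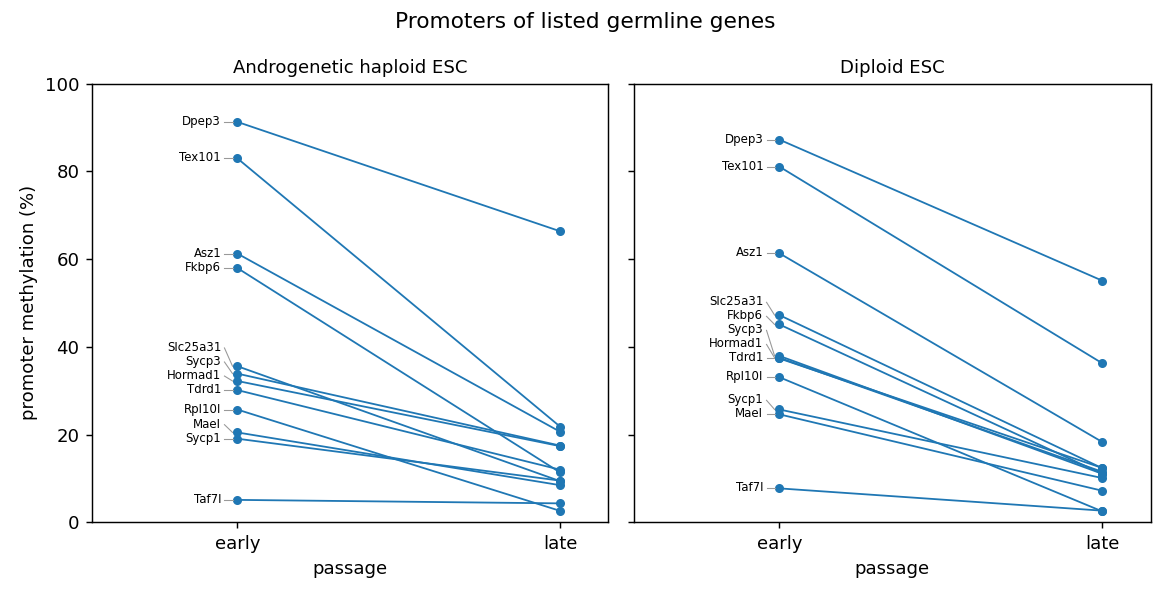
Promoter methylation in percent (vertical axis) of the 12 measured germline genes at early and late passage in ahESCs and diploid cells. Each line joins the values of 1 gene in 2 libraries. All 12 lines slope down in both panels, 4 by at least 25 points in ahESCs and 8 in diploid cells.

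At early passage, ahESCs and diploid cells differed at imprinted regions and hardly anywhere else. Of 18 maternally methylated germline windows 14 were lower in ahESCs by at least 25 points, among them Peg13-Trappc9 (62.6% in diploid cells, 4.05% in ahESCs), Inpp5f (57.6% and 2.10%), Igf2r-Airn (56.1% and 1.35%) and Snrpn-Snurf (54.3% and 2.85%). Over 24234 tiles, 28 were lower and 20 higher. The mean over all exonic CpGs was 12.8% in diploid cells and 12.7% in ahESCs. Of the paternally methylated windows, Rasgrf1 stood at 72.4% and 57.0%, the H19 promoter at 58.4% and 35.1% and the Meg3 promoter at 51.2% and 44.1%.

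The window means were 46.2% (SD 21.6 over 18 windows) in diploid cells and 7.85% (SD 18.98) in ahESCs. Promoters gave the same picture, with 11 lower and 2 higher of 3885. The 11 include the imprinted genes Snrpn, Nap1l5, Peg13, Zrsr1, Peg10, Plagl1 and Gnas, which overlap the windows, and Nnat, an imprinted gene outside them, at 44.6% and 10.5%. Among the promoters that were higher was C330024D21Rik, at 15.51% and 52.3%. None of the 12 measured germline genes passed 25 points, with a median difference of -4.00. Both libraries are of the first set.

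Early phESCs had lower methylation than early diploid cells, both at imprinted regions and across the genome. Of 18 maternal windows 15 were lower by at least 25 points, for instance Snrpn-Snurf (54.3% in diploid cells, 1.24% in phESCs). Cdh15 (86.5%, 24.9%) was also among them, but it stood at 82.5% in early ahESCs. The paternally methylated Rasgrf1 window was lower too, with a difference of -37.8 points. So were the H19 promoter (58.4%, 20.7%) and the Meg3 promoter (51.2%, 2.82%), while Nesp and Cdkn1c were low in both cell types. Of 24035 tiles 5746 were lower and 13 higher. The mean over exonic CpGs that reached 20% in another library was 50.6% in diploid cells and 27.8% in phESCs. Fkbp6, Asz1 and Tex101 were the 3 germline genes of 12 that were lower by at least 25 points, and the list had a median difference of -16.1 at percentile 90.8.

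Of 3991 promoters 547 were lower and 6 higher. The lowest relative to diploid cells outside imprinted windows were Dnajc5g (64.7% and 8.45%), Brpf3, a subunit of a histone acetyltransferase complex (74.7% and 18.8%), and Rps26-ps1 (82.7% and 27.6%), and Tet1, an enzyme that oxidises methylcytosine, stood at 64.7% and 13.6%. Higher promoters were Abcc9 (9.005% and 51.0%), Fv1 and Miip (1.39% and 38.7%) and 2810429I04Rik (1.79% and 31.4%). Against early ahESCs, phESCs had 5446 lower and 9 higher tiles of 23965. There Traip stood at 60.5% in ahESCs and 0.958% in phESCs, and Cdh15 was the 1 maternal window lower by at least 25 points. All these libraries are of the first set.

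At late passage the 3 stem cell types differed in few tiles, with maternal windows low in all of them. Among exonic CpGs that reached 20% in another library, the mean was 24.0% in ahESCs and 18.6% in diploid cells. For phESCs and diploid cells it was 22.3% and 17.5%. The window means were 5.80% in ahESCs, 4.83% in phESCs and 2.37% (SD 2.77) in diploid cells, and no maternal window differed by 25 points in any pair. With the median over the cytosines of each window they were 1.68%, 4.70% and 1.42%, so the order of the types depends on this choice. Late ahESCs had 115 higher and 9 lower tiles than late diploid cells, of 21877, and 580 higher and 60 lower over all cytosines that reached 20% elsewhere. Late phESCs had 125 higher and 14 lower of 20961 against diploid cells, and 50 higher and 74 lower of 20691 against ahESCs, a balance that turned to 588 higher and 334 lower over all cytosines that reached 20% elsewhere. Arhgef25 was higher in ahESCs than in diploid cells (15.8% and 51.4%), and Tmem267 was higher in phESCs (3.24% and 58.2%).

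Fv1 and Miip were lower in both haploid types than in late diploid cells, at 6.43% against 33.3% in ahESCs and 0.979% against 28.8% in phESCs. Col6a5, a collagen gene, was also lower in ahESCs (43.7% in diploid cells and 17.3%). CCGG sites, which remain in promoters, stood 21.6 points below other CpGs of methylated tiles in late ahESCs and 4.36 below in late diploid cells. These gaps rest on 493 and 145 tiles, chosen as 60% or more at the other CpGs. Over all exonic CCGG sites measured in both libraries the direction was the opposite, at 20.9% in late ahESCs and 15.9% in late diploid cells. Whether CCGG sites lower the ahESC promoters relative to diploid cells was not tested. None of the measured germline genes passed 25 points in these 3 comparisons, with median differences of 0.914, 3.12 and 1.27 points. The comparisons with diploid cells cross the library sets, and the late phESC library differs from the late ahESC library in its share of CCGG sites.

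**Figure D3:**
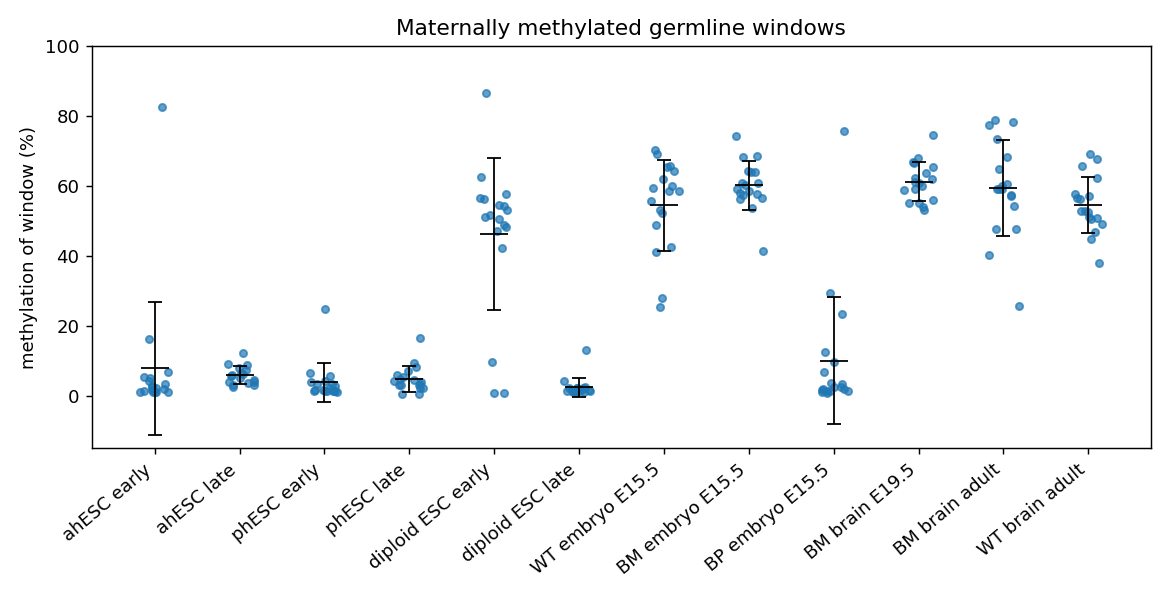
Methylation in percent (vertical axis) of each maternally methylated germline window in each library (horizontal axis). Points are windows, of which 17 were measured in late ahESCs and 18 in every other library, and the black marks give the mean and 1 SD over windows, which are not replicates. The means lie between 2.37% and 10.01% in all haploid cells, late diploid cells and the BP embryo, and between 46.2% and 61.2% in the other libraries.

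The BM embryo, made from a phESC and an oocyte, kept a WT level of methylation over most autosomal sequence and was far higher than the WT embryo on chromosome X. Of 460 tiles on X, 222 were higher and none lower, and the median X tile was higher by 24.6 points. Of 23703 autosomal tiles 38 were higher and 5 lower, with a median difference of -0.00523 points. Promoters on X that rose include Nono, an RNA-binding protein gene (0.701% in WT, 50.7% in BM), Efnb1, which encodes an ephrin (1.33%, 43.0%), and Rlim, a ubiquitin ligase gene linked to X inactivation (0.563%, 40.9%). At imprinted regions the maternal windows had a mean of 60.2% (SD 7.01) in BM and 54.4% (SD 12.97) in WT, and the H19 promoter stood at 11.8% and 48.2%.

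CpGs of dense tiles on X had a mean of 30.3% in the BM and 3.30% in the WT embryo, while those on autosomes had 3.54% and 3.59%. The WT embryo library has values at 1470 positions of chromosome Y and the BM embryo library at 51, so on X the BM origin cannot be told apart from a difference in sex chromosomes. Of 277 X promoters 210 were higher and none lower. Outside X, 9 promoters were higher, led by Ccer1 on chromosome 10 (39.2% in WT, 78.2% in BM), and 3 were lower, namely Nfs1 and Romo1 with a shared promoter (31.1%, 0.934%) and Snrpn (70.9%, 42.0%).

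Among the maternal windows Kcnq1ot1 (25.3% in WT, 60.7% in BM), Slc38a4 (42.5%, 74.3%) and Impact (28.0%, 56.3%) were higher by at least 25 points and none was lower by as much. Kcnq1ot1 and Impact were the lowest and second lowest windows of the WT embryo. They stood at 50.4% and 57.0% in the WT adult brain, so for them it was the WT embryo value that was low. Snrpn-Snurf stood at 65.7% and 41.3%. Of the paternally methylated regions, the H19 promoter was lower and the Meg3 promoter higher (35.5%, 60.6%), and Rasgrf1 stood at 47.0% and 28.1%. None of the 12 measured germline genes passed 25 points, and their median was 90.3% in WT and 89.7% in BM. Both libraries are of the first set.

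**Figure D4:**
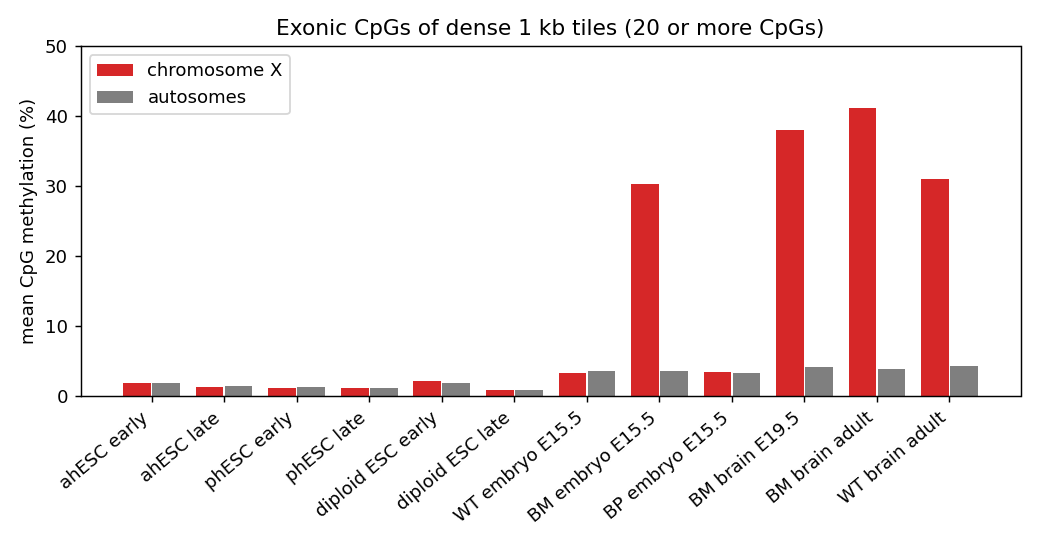
Mean methylation in percent (vertical axis) of exonic CpGs in dense 1 kb tiles on chromosome X and on autosomes in each library (horizontal axis), 1 library per pair of bars. The X bars stand at 30.3% in the BM embryo, 38.0% in the BM E19.5 brain, 41.1% in the BM adult brain and 31.1% in the WT adult brain, and at most at 3.49% in the other libraries.

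The BP embryo, made from an ahESC and a sperm in an enucleated oocyte, had a mean exonic level close to WT. It lacked methylation at nearly all maternally methylated windows called imprinted here. Of 18 maternal windows 16 were lower than in WT by at least 25 points, among them Mcts2-H13 (70.2% in WT, 1.51% in BP), Nap1l5-Herc3 (69.1%, 2.59%), Snrpn-Snurf (65.7%, 1.19%) and Grb10, a growth factor adaptor gene (61.8%, 2.55%). The H19 promoter (48.2%, 73.4%) and the Meg3 promoter (35.5%, 76.3%), which are methylated on the paternal copy, were higher. These BP values rest on 8 and 7 cytosines and the WT values on 12 and 17, which are not matched positions. The mean over exonic CpGs that reached 20% in another library was 66.7% in both embryos. Of 23079 tiles, 73 were higher and 50 lower, and at a threshold of 40 points 7 were higher and 15 lower. Over all cytosines that reached 20% elsewhere, 533 tiles were higher and 87 lower, and with 5 CpGs per tile 18 and 34.

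The mean over the maternal windows was 10.01% (SD 18.2) in BP and 54.4% (SD 12.97) in WT. The 2 that were not lower by 25 points were Kcnq1ot1 (25.3%, 1.28%) and Cdh15 (52.4%, 75.6%). Peg13-Trappc9 (64.3%, 29.2%) and Gnas-1A (48.8%, 23.3%) kept more methylation in BP than the other windows that were lower. Rasgrf1 stood at 47.0% and 43.8%. Of 2977 promoters 20 were lower and 19 higher. Outside the windows the imprinted gene Nnat (60.03%, 3.08%), Mir5046 (41.8%, 9.37%) and Cyb5b, a cytochrome gene (34.4%, 2.72%), were lower. Ccer1 (39.2%, 76.0%), the endoglin gene Eng (22.4%, 56.4%) and Fam32a (13.9%, 42.2%) were higher. None of the 12 germline genes passed 25 points, and the X tiles had 2 higher and 3 lower of 375. Both libraries are of the first set.

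The adult BM and WT brains had nearly the same methylation, with differences on chromosome X, at 1 imprinted window and at a few other sequences. The mean over exonic CpGs was 16.2% in WT and 16.1% in BM, and 13 of 21561 tiles were higher and 7 lower, against 11 higher and 14 lower over all cytosines that reached 20% elsewhere. On X 10 of 417 tiles were higher and 1 lower, with a median difference of 6.89 points. The Peg3-Usp29 window was higher in BM (44.8% in WT, 73.4% in BM), and no other maternal window of 18 differed by 25 points. These values rest on 9 and 8 cytosines, so the window drops out where at least 10 are required. The WT embryo (60.1%) and the BM E19.5 brain (61.8%) lay between them. The promoters that were higher were Gpi1, which encodes a glycolytic enzyme (41.5%, 72.3%), Gabrq, a receptor subunit gene on X (36.0%, 63.2%), and Mrpl19 of the mitochondrial ribosome (28.2%, 54.0%).

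No promoter of 4402 was lower by 25 points. The maternal windows had means of 54.5% (SD 8.07) in WT and 59.4% (SD 13.7) in BM, with Snrpn-Snurf at 37.9% and 25.8% and Plagl1 at 62.2% and 78.1%. The H19 promoter stood at 37.0% and 21.01%. The 12 germline genes had medians of 80.4% and 80.1%. Both libraries are of the second set. Chromosome Y positions with a value numbered 2246 in the WT and 890 in the BM library, so on X the BM origin cannot be told apart from a difference in sex chromosomes here either. Of 953 Y positions found in the first set only in the diploid, WT embryo and BP embryo libraries, 598 and 46 had a value. CpGs of dense tiles on X had a mean of 31.1% in the WT and 41.1% in the BM adult library, against 3.30% in the WT embryo. The WT adult library thus had both Y values and a high X level, and how many animals it holds was not examined.

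Between E19.5 and adulthood the BM brain kept its methylation at most exonic CpGs outside CCGG sites, and some promoters differed both ways. The mean over exonic CpGs outside CCGG sites was 15.6% at E19.5 and 15.4% in the adult, and 181 of 18791 tiles were lower and 56 higher. Over all cytosines that reached 20% elsewhere, which include CCGG sites, the mean was 73.0% and 64.7%, with 1743 tiles lower and 72 higher. The Meg3 promoter, of a maternally expressed noncoding RNA, stood at 54.4% and 19.7%, Snrpn-Snurf at 55.0% and 25.8% and Inpp5f at 74.6% and 47.7%. The Plagl1 window stood at 53.9% and 78.1%, Peg10-Sgce at 55.1% and 78.9% and Nap1l5-Herc3 at 61.2% and 77.3%, and of the 18 maternal and 4 paternally methylated windows measured in both libraries 0 were higher by 25 points. The Plagl1 promoter was higher (54.1%, 84.8%). Of 12 germline genes 2 were lower by at least 25 points, namely Tex101 (94.2%, 52.3%) and Sycp3 (81.7%, 52.8%). The Tex101 values rest on 6 cytosines, the fewest allowed. Over the 14 cytosines compared with the WT adult brain, Tex101 stood at 75.1% in the BM adult brain. Gpi1 was higher (18.4%, 76.0%), as were Cyb5b (2.64%, 43.1%), Odc1, a polyamine synthesis gene (37.4%, 75.9%), and Ndufs6 of the respiratory chain (2.14%, 39.6%).

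Of 2556 promoters, 81 were lower and 17 higher. The largest falls outside the windows were at Rpl13-ps6 (93.6%, 45.5%), Tppp3 (91.3%, 47.4%) and Gprc5b (80.3%, 39.3%). The means of the maternal windows were 61.2% (SD 5.66) and 59.4% (SD 13.7). The comparison crosses the library sets, and at CCGG sites the mean was 37.5% at E19.5 and 21.9% in the adult. Promoters and windows contain such sites, since these could be removed from exons only, and a lower adult value there cannot be told apart from the set.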

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

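The passage tests on feeder cells and the test of age at all CpGs were chosen only after the result was seen. The tests of the library set and of filled-in read ends were written before their values were computed. The differences between groups listed here were not tested.

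Methylation in the tiles that fell in ahESCs was lower by 39.2 points on average at late passage, and the libraries come from both library sets. If libraries of the second set read lower at every methylated CpG, the same tiles should also be lower in the adult than in the E19.5 BM brain, and 3808 of the 4975 tiles were measured there. Their mean difference was -3.27 points (SD 7.99 over tiles, CpGs outside CCGG), from 87.2% to 83.9%, so this explanation is unlikely to account for most of the loss. Feeder or other somatic cells in the early library would carry maternal imprints, but the median maternal window of early ahESCs was 2.28%. This value speaks against feeder cells as the main source in ahESCs. In early diploid cells, of a single library set, the median was 51.4%, which cannot tell feeder cells from imprints of the cells themselves. The second lowest window, Slc38a4, was used there instead and was 0.852%. That choice rests on few windows, and feeder cells were not measured, so no conclusion is drawn for diploid cells. A loss in the cells themselves may remain as the explanation, which these libraries cannot test without replicates.

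CCGG sites were lower by 15.6 points in the adult than in the E19.5 BM brain. Loss with age at all CpGs would also lower the CpGs outside CCGG sites, and these differed by -0.250 points, which makes it unlikely. Unmethylated bases filled in at read ends in the second library set could lower CCGG sites, and CCGG sites minus other CpGs of methylated tiles was -21.6 points in the late ahESC library, -37.8 in the adult BM and -35.5 in the adult WT brain. In the late phESC library, which shares few positions with the other 3, the same difference was 5.88 points over 19 tiles. The test required the gap in all 4 libraries, so filled-in ends stay open as an explanation.

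Early and late passage differed in how far the haploid cells stood from diploid cells. The mean difference of ahESCs from diploid cells was -0.155 points early and 1.53 late, and that of phESCs was -5.47 early and 0.999 late. Over the maternal windows it was -38.4 early and 4.05 late in ahESCs, and -42.4 early and 2.46 late in phESCs. From early to late passage the maternal windows differed by 2.34 points in ahESCs, 1.02 in phESCs and -43.9 in diploid cells. BM differed from WT by 0.618 points in the embryo and by -0.126 in the adult brain.

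Unplaced sequence of chromosome Y had values at 4124 positions in the late ahESC, 2348 in the late phESC, 2209 in the adult BM and 7697 in the adult WT library. Cytosines of GCAC had a mean of 2.26% in the BM E19.5 brain.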

How the results depend on the processing

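The alternatives were chosen before the data were examined, except for 3 that were chosen after seeing the data: CCGG sites included, and the means and the tiles over all cytosines that reached 20% in a library outside the pair. The planned minimum of 10 reads, no minimum, read-weighted mean and Fisher test were not run, since read depth was not analysed here. Depth is unknown, so counting error cannot be given for any value. In simulated data at 20 reads per CpG, the 25-point rule called 94 of 100 planted rises and 77 of 100 falls of 30 points, and 0 rises and 3 falls of 15 points. No paired analysis was possible because the labels give no replicate numbers and the comparisons come from no test. Early and late passage could be paired only over the 3 cell types, in a test chosen after the result was seen. The sign changed for the following small differences. The mean difference of the BP from the WT embryo went from -0.132 to 0.0229 with CCGG sites and to 1.39 with the wider set. With 500 bp on each side of the start site, the developmental list went from -4.18 to 0.134 in early phESCs against diploid cells and from 0.121 to -0.685 in the BM embryo, and the neural list from 0.188 to -0.857 in the BP embryo. A difference was taken as kept if it had the same sign and lay within a factor of 1.5, or if it shifted by less than 1 point. Several mean differences are themselves under 1 point, and for them this rule is lenient. That of the BM from the WT embryo counts as kept though it went from 0.618 to 0.252 without chromosomes X, Y and M. A count was kept within a factor of 1.5, and a window mean if it shifted by no more than 1 SD over its windows, or over its cytosines where 1 window was measured, which is a wide tolerance.

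Of 13 mean differences, 13 were kept over the CpGs measured in all 12 libraries, 13 without chromosomes X, Y and M, 12 with CCGG sites and 2 with the wider set of cytosines. The largest shifts of a mean difference were 1.34 points over the CpGs in all 12 libraries, 0.366 without X, Y and M, 3.69 with CCGG sites and 25.8 with the wider set, which by its construction leaves out unmethylated cytosines. Of the window means, 34 of 34 were kept over all measured windows and in the middle part of each window, 25 of 25 with at least 10 cytosines and 33 of 34 with the median. Window means still shifted by up to 17.1 points over all measured windows, 15.9 with at least 10 cytosines, 12.7 with the median and 1.91 in the middle part. Over all measured windows the paternal germline mean of late ahESCs went from 31.3% to 18.8%. With at least 10 cytosines the paternal somatic mean of the BP embryo went from 58.9% to 43.0%, because the H19 and Meg3 promoters drop out. With 500 bp on each side of the start site, 13 of 13 promoter counts were kept each way and 20 of 26 list medians. Tiles of 500 bp kept 13 of 13 counts of higher tiles and 12 of 13 of lower tiles. The stricter tile rules lowered most counts by their construction, and the wider set adds tiles outside exons. The balance of higher and lower tiles turned with the wider set in late phESC against ahESC and in the adult brain, at 40 points in the adult brain and the BP embryo, and with 5 CpGs per tile in the BP embryo. Promoters of the BP embryo turned from 19 higher and 20 lower to 20 and 19 with 500 bp on each side.

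With all cytosines that reached 20% outside the pair, exonic or not, the mean differences in points were -25.9 for ahESC passage, -5.54 for phESC passage, -33.5 for diploid passage, -1.38 for early ahESC against diploid, -22.6 for early phESC against diploid, -21.2 for early phESC against ahESC, 7.05 for late ahESC against diploid, 3.65 for late phESC against diploid, 2.47 for BM against WT embryo, 1.39 for BP against WT embryo, -8.32 for BM adult against E19.5 brain. With CCGG sites included the mean difference was -3.94 for BM adult against E19.5 brain. With at least 5 CpGs per tile the numbers of higher tiles were 1 for ahESC passage, 3 for phESC passage, 8 for early ahESC against diploid, 3 for early phESC against diploid, 2 for early phESC against ahESC, 32 for late ahESC against diploid, 38 for late phESC against diploid, 13 for late phESC against ahESC, 18 for BP against WT embryo, 6 for BM against WT adult brain. The numbers of lower tiles were then 1958 for ahESC passage, 42 for phESC passage, 2755 for diploid passage, 18 for early ahESC against diploid, 2302 for early phESC against diploid, 2263 for early phESC against ahESC, 2 for late ahESC against diploid, 3 for late phESC against diploid, 26 for late phESC against ahESC, 0 for BM against WT embryo, 0 for BM against WT adult brain, 49 for BM adult against E19.5 brain. At a threshold of 40 points the numbers of higher tiles were 0 for ahESC passage, 0 for phESC passage, 0 for diploid passage, 3 for early ahESC against diploid, 1 for early phESC against diploid, 1 for early phESC against ahESC, 4 for late ahESC against diploid, 9 for late phESC against diploid, 4 for late phESC against ahESC, 20 for BM against WT embryo, 7 for BP against WT embryo, 0 for BM against WT adult brain, 7 for BM adult against E19.5 brain. The numbers of lower tiles at 40 points were 2135 for ahESC passage, 10 for phESC passage, 13 for early ahESC against diploid, 1483 for early phESC against diploid, 1226 for early phESC against ahESC, 1 for late ahESC against diploid, 0 for late phESC against diploid, 10 for late phESC against ahESC, 0 for BM against WT embryo, 15 for BP against WT embryo, 1 for BM against WT adult brain, 19 for BM adult against E19.5 brain. With the wider set of cytosines, at least 6 per tile, higher tiles numbered 16 for ahESC passage, 14 for diploid passage, 166 for early ahESC against diploid, 55 for early phESC against diploid, 38 for early phESC against ahESC, 580 for late ahESC against diploid, 275 for late phESC against diploid, 588 for late phESC against ahESC, 732 for BM against WT embryo, 533 for BP against WT embryo. Lower tiles of that set numbered 25146 for ahESC passage, 492 for phESC passage, 36520 for diploid passage, 190 for early ahESC against diploid, 28285 for early phESC against diploid, 23684 for early phESC against ahESC, 60 for late ahESC against diploid, 89 for late phESC against diploid, 334 for late phESC against ahESC, 16 for BM against WT embryo, 87 for BP against WT embryo, 14 for BM against WT adult brain, 1743 for BM adult against E19.5 brain. With tiles of 500 bp the number of lower tiles was 11 for BM against WT adult brain. The median over cytosines gave a mean of 1.68% over the maternal windows of late ahESCs. With 500 bp on each side of the start site, the neural list had medians of -30.4 for diploid passage, -17.8 for early phESC against diploid, 1.66 for late ahESC against diploid and -0.857 for BP against WT embryo, and the developmental list -1.46 for diploid passage and 0.134 for early phESC against diploid. For the window median, the lists and the tiles of 500 bp, the cause was not tested.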

Other observations

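Both tests of the GCA cytosines were written before their values were computed, after a first look at the levels. That look had shown GCA above GCC and GCT in the brain libraries, at 1.36%, 0.580% and 0.595% in the BM E19.5 brain. GCAC is part of GCA, so both tests largely restate this pattern.

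The file also lists cytosines outside CpG, in the sequence GC. In the BM E19.5 brain the mean at GCAC was 2.26%, against 0.860% in the BM embryo, over 44598 cytosines. Methylation of CAC, known of neurons, would raise GCAC more than GCT, and the rise was larger by a ratio of 6.504, so non-CpG methylation may explain it. Incomplete conversion alike at every cytosine would raise GCC as much, but the ratio of GCAC to GCC was 24.8. The pattern seen first already held this inequality, so the ratio is not separate evidence against incomplete conversion. The size of this ratio rests on a rise of only 0.0566 points at GCC, while GCT rose by 0.215 and GCAT by 0.563. At positions shared with late ahESCs, GCAC had 2.39% in the WT adult brain against 1.57% in late ahESCs. For the BM adult brain the values were 2.17% and 1.59%. The adult brains and the E19.5 brain were not compared at shared positions, so their levels cannot be ranked.

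Values on chromosome Y numbered 1470 positions in the WT, 51 in the BM and 1185 in the BP embryo, 1587 in early and 1489 in late diploid cells, 22 in early ahESCs, 97 in early phESCs and 106 in the BM E19.5 brain. The libraries of the second set had 1161 in late ahESCs, 654 in late phESCs, 890 in the adult BM and 2246 in the adult WT brain. Of 953 Y positions with a value in both diploid, the WT embryo and the BP embryo libraries and in no other library of the first set, 12 had a value in late ahESCs, 5 in late phESCs, 46 in the adult BM and 598 in the adult WT brain.

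The promoter of Fv1 and Miip stood at 1.23% in early and 33.2% in late diploid cells and at 35.6% in early and 1.21% in late phESCs. Abcc9 stood at 7.49% in early and 32.9% in late diploid cells.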
